A study of Mus musculus with 12 samples.

How the data were processed

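Expression profiles of mouse breast tumours carrying the ETV6-NTRK3 fusion were analysed as log ratios against a common reference. Per the labels, total RNA of each of 12 samples was labelled with Cy5, and a mouse reference RNA with Cy3, and both were hybridised to the same array. The labels give 1 group, Wap-Cre ETV6-NTRK3, in which Cre recombinase under the promoter of the milk protein gene Wap is paired with the fusion of the genes Etv6 and Ntrk3. The samples are called tumours 1 to 12 here, a numbering that only names them. The composition of the reference, and the meaning of a word for mixing in each title, are not given in the sources used here. Nothing in the labels says that the tumours came from separate animals, and the titles of tumours 6 and 7 share the token D14. The p-values therefore measure the spread between these samples, part of which may be technical.

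The authors deposited 1 value per probe and array for 22575 probes, used here as log2 ratios. The steps that made them (background correction, normalization and any spot filter) are not given in the sources used here. The base of 2 was taken from the range, −9.602 to 8.038, since base 10 would give ratios far beyond what a scanner measures. The direction was not stated in the file. It was taken as tumour over reference, which is likely because the labels give Cy5 to the tumour and Cy3 to the reference. The signs of milk protein and luminal keratin genes (positive) and of liver, muscle and neuron genes (negative) were also looked at in this choice, so they give no independent evidence of direction. Array medians lay between −0.005 and 0.01, so the deposited values are centred near 0. Per array, 14 to 134 values were missing (0.062% to 0.594%), for a reason not stated. Spot intensities and background flags were not used here, so that a very low or very high ratio can be a bound set by background in either channel or by saturation, and the number of arrays limits the precision. All arrays had the same dye orientation, and no dye swap was analysed. A dye bias particular to a gene therefore stays in its ratio against the reference, which matters most for small ratios, and cancels in differences between tumours.

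Probes were named from the platform annotation. One gene symbol was given for 18658 probes, several for 30 and none for 3887, and only the first kind was used. The Entrez identifiers of 18445 probes matched a RefSeq gene table (GRCm38.p6), used for names alone. Probes of a gene were averaged, giving 16887 genes, 1247 of them with 2 or more probes. For genes with 2 or more probes the median gap between the means of the compared pair was 0.45 log2 units. The 16881 genes with values on at least 9 of 12 arrays were tested. No pair of arrays held identical values.

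Ratios were tested against 0 with limma 3.58.1 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05) in R 4.3.3. A ratio beyond 2-fold was tested with treat at a log2 threshold of 1. The reference is 1 RNA and no sample of a group, so these tests leave out its own spread. For each of 28 gene lists, the median log2 ratio of the list minus that of all genes was taken per array and tested with an exact two-sided sign-flip test, adjusted over the 28 lists. The smallest p this test can give is 0.000488. The competitive test cameraPR was run with a preset correlation of 0.01 and with an estimated one. A list score is the mean of gene-centred log2 ratios of the members measured on all arrays. Each of 16 pairs of scores was correlated over the tumours with 100000 permutations. The SD of each score was set against 10000 random lists matched on size and on the SD of their genes. The description field holds 3 dates of unstated meaning, called date 1 (6 tumours), date 2 (3 tumours) and date 3 (3 tumours). They were tested as batches with limma's F test and against 100 splits of the tumours. The likeness of tumours 6 and 7 was ranked among all 66 pairs, where the smallest one-sided p is 0.0152. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

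The tests, lists, score pairs and most alternatives were fixed before the data were examined. The random lists, the slopes set against the neuron score, the fits without both D14 tumours, the variation without each tumour in turn, and 2 of the likeness settings (without the proliferation and fibroblast lists, and after regression on these scores) were added after seeing the data. The genes to be named were fixed by rule: the 10 highest and 10 lowest means beyond 2-fold with 1 sign on every array, all AP-1 subunits, Etv6 and Ntrk3, 2 to 4 members per list with the largest ratios, the 10 largest SDs, and the 4 smallest p-values between dates. Others are said to be chosen after their values were seen. No single-symbol probe for Etv6 was used here.

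The limma steps were tested on simulated data for 16881 genes, with independent noise at the real SDs and 50 genes shifted by each amount. In the real data limma called 67.1% of genes against the reference, so recovery and false calls there may differ. Against the reference, 62% of genes shifted by 0.5 log2 units, 98% of those shifted by 1 and 100% of those shifted by 2 were recovered, with 7 false calls among 187. Treat called 96% of those shifted by 2 and 98% of those shifted by 3. Between dates, 0% of genes shifted by 0.5, 42% of those shifted by 1, 90% of those shifted by 2 and 100% of those shifted by 3 were recovered, with 8 false calls among 124. The shift was put on date 1 alone, and a shift on another date was not simulated. For the list shift, 10 of 10 lists shifted by 0.5 were recovered and 0 of 18 others were called, in 16431 simulated genes that were independent, unlike real genes. All genes outside the shifted lists had a true mean of 0 there, also unlike real genes. The simulation therefore does not show how often the sign-flip test would call a list of arbitrary genes. The cameraPR and score correlation steps were not simulated.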

Results

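The series profiled mouse breast tumours with the ETV6-NTRK3 fusion, which joins part of the transcription factor ETV6 to the kinase domain of the receptor NTRK3. The title of the series places the origin of these tumours in alveolar progenitors and ties them to the AP-1 complex. Each of 12 tumours was hybridised on its own 2-colour array against a common mouse reference RNA. No normal mammary gland was analysed here, so each ratio states a level against that reference and not against the tissue of origin. The correlation between arrays over probes ran from 0.738 to 0.917 with a median of 0.839, and tumour 7 had the lowest median correlation with the others, 0.779.

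The tumours had far higher levels of milk protein transcripts than the reference and far lower levels of liver, muscle and nerve transcripts. The casein genes Csn2 (7.37 ± 0.51, SD, n = 12, on the log2 scale), Csn1s2a (6.62 ± 0.36) and Csn1s1 (6.46 ± 0.43) had the highest ratios. Csn3, another casein, followed at 4.28 ± 0.82, together with Elf5, a transcription factor of alveolar differentiation (4.21 ± 0.36), and Lcn2, a secreted iron-siderophore binding protein (4.24 ± 0.18). Plekhs1 (5.27 ± 0.29), Plet1 (4.47 ± 0.64), Itprid1 (4.37 ± 1.08) and Inhbb, an inhibin subunit (3.98 ± 0.63), completed the 10 highest. At the other end stood Fabp1, a liver fatty acid binding protein (−8.26 ± 0.50), Itm2a (−7.93 ± 0.82), Atp1b4 (−7.77 ± 0.46), the muscle protein gene Myot (−7.47 ± 0.48) and the retinol carrier gene Rbp4 (−7.36 ± 0.31). The urea cycle gene Cps1 (−7.34 ± 0.57), the fibrinogen gene Fgg (−7.08 ± 0.51), Fhl1 (−6.89 ± 0.44), Smpx (−6.86 ± 0.44) and the apolipoprotein gene Apoh (−6.83 ± 0.19) completed the 10 lowest. All 20 had the same sign in every tumour. Since intensities were not used here, ratios at either end can be limited by background or saturation, and their order is uncertain. The direction of the ratios was not stated and was taken as tumour over reference. The signs of milk, luminal, liver, muscle and neuron genes were looked at in that choice, so they are no independent finding of direction.

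Over all 16881 genes, limma called 11330 different from the reference (67.1%), 5376 of them higher and 5954 lower. Beyond 2-fold, 2362 genes passed, 498 higher and 1864 lower. Within date 1, date 2 and date 3 alone, limma called 9677, 5901 and 6293 genes, and 2101, 1514 and 1693 beyond 2-fold, from fewer arrays. Ntrk3 was slightly lower than the reference (−0.42 ± 0.37, n = 11, limma adjusted p = 0.00292). Whether the Ntrk3 values include transcripts of the fusion was not checked.

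The mammary lists set the tumours apart from the reference. Of 15 measured milk secretion genes 13 were higher and 1 lower, and the list lay 3.20 ± 0.64 log2 units above all genes (SD, n = 12, higher in 12 of 12 tumours, exact sign-flip adjusted p = 0.000911). Of 13 alveolar and luminal progenitor genes 12 were higher, with a shift of 2.01 ± 0.40 in 12 of 12 tumours. Examples are Ehf, an epithelial ETS factor (3.79 ± 0.67), the co-receptor gene Cd14 (3.25 ± 0.83) and the receptor kinase gene Kit (2.75 ± 0.99). Of 15 luminal epithelial genes 14 were higher, with a shift of 1.79 ± 0.26 in 12 of 12 tumours. They include the keratin genes Krt19 (2.75 ± 0.80) and Krt18 (2.50 ± 0.17), the tight junction gene Cldn3 (2.66 ± 0.33) and the adhesion gene Epcam (2.50 ± 0.34). Both lists had an exact sign-flip adjusted p of 0.000911, and these 3 lists also passed cameraPR with an estimated correlation (adjusted p = 0.000212, 1.88e-06 and 0.000591).

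Basal and hormone-sensing genes gave a mixed picture. Among 14 basal and myoepithelial genes 4 were higher and 7 lower. The smooth muscle genes Cnn1 (−3.49 ± 0.75), Myh11 (−3.36 ± 0.61) and Acta2 (−2.34 ± 0.44) were lower, and the laminin gene Lamb3 was higher (1.91 ± 0.75). The list fell by 0.36 ± 0.51 in 9 of 12 tumours (exact sign-flip adjusted p = 0.0348), but did not pass cameraPR (adjusted p = 0.695). Without tumour 1, 3, 5, 6, 7, 8, 9 or 12 the shift lay between −0.36 and −0.26, with an exact adjusted p between 0.0501 and 0.0671. It was −0.36 with the D14 tumours averaged (exact adjusted p = 0.0559) and −0.35 without them (exact adjusted p = 0.0820). Among 10 hormone-sensing luminal genes 2 were higher, Prom1 (2.18 ± 0.87) and the luminal factor Gata3 (1.51 ± 0.43). Another 3 were lower, among them Wnt4 (−1.26 ± 0.51) and Cited1 (−0.29 ± 0.34). Within date 1 Cited1 did not differ from the reference (−0.02, limma adjusted p = 0.895). That list had a shift of 0.00 ± 0.14 (exact sign-flip adjusted p = 0.930). By the mean of its members it lay at 0.20 (adjusted p = 0.00521).

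**Figure D1:**
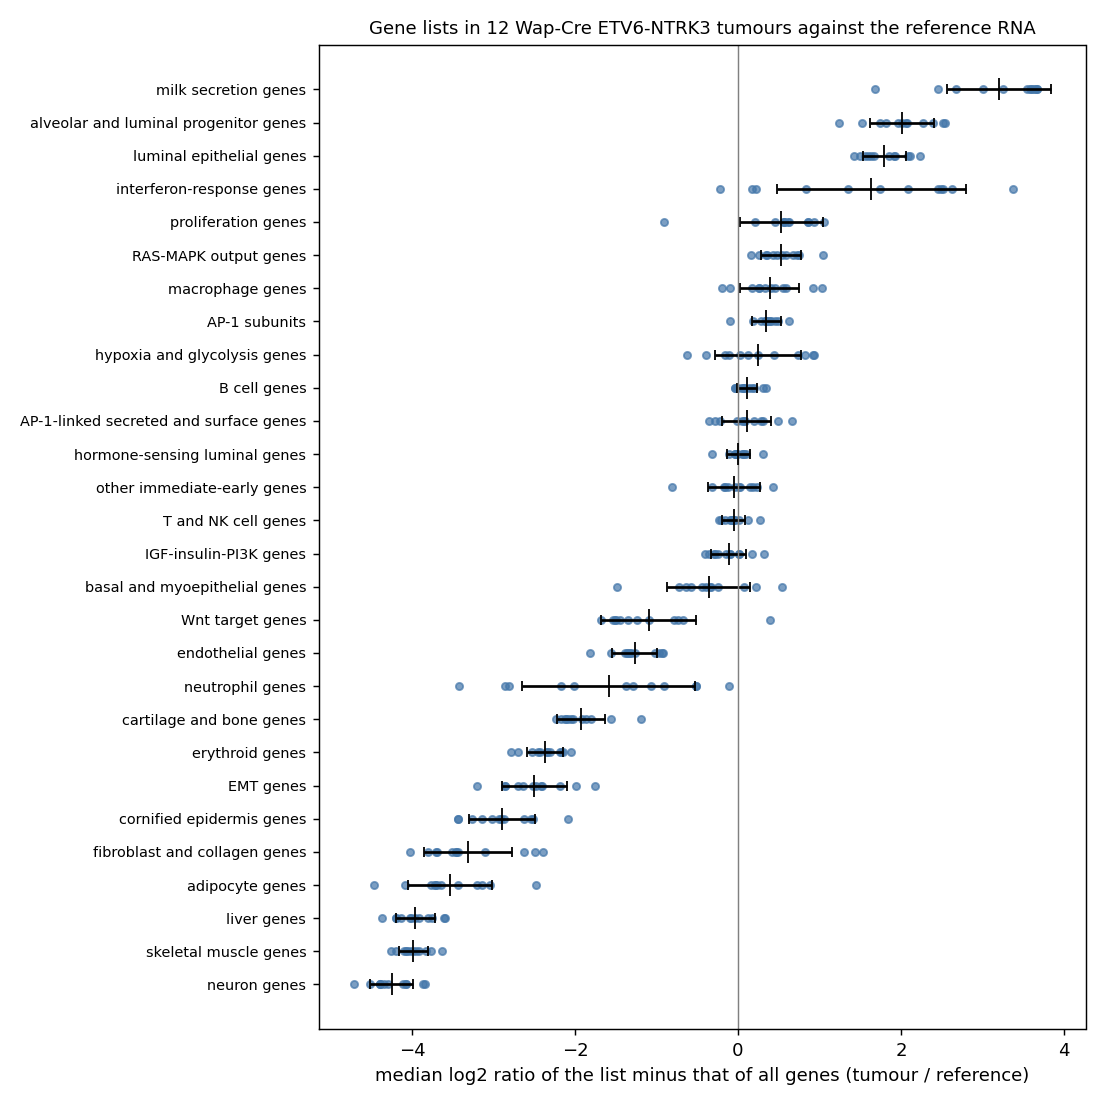
Median log2 ratio of each of 28 gene lists minus that of all genes (horizontal axis, tumour over reference), with 1 point per tumour, a vertical tick at the mean of 12 tumours and a bar of 1 SD on each side. Milk secretion genes lay highest at 3.20 and neuron genes lowest at −4.25.

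The question named in the title concerns AP-1, the dimeric transcription factor built from Fos, Jun and related subunits. Transcripts alone were measured here, so these ratios do not give the level or activity of AP-1 protein. Of 12 measured subunits 7 were higher than the reference, 1 was lower and 4 did not pass, and the counts adjusted over the list alone were the same. Junb (1.52 ± 0.49, n = 12, limma adjusted p = 4.61e-08) was the only subunit past the test beyond 2-fold (adjusted p = 0.00467). Batf (1.43 ± 0.91), Atf2 (1.02 ± 0.35), Fosl1 (0.56 ± 0.26), Atf3 (0.44 ± 0.48), Fos (0.44 ± 0.49) and Fosb (0.43 ± 0.21) were also higher. Jdp2, a subunit known as a repressor, was lower (−0.42 ± 0.30), and Fosl2 (−0.17 ± 0.29), Jun (−0.14 ± 0.57), Jund (−0.11 ± 0.58) and Batf3 (−0.00 ± 0.49) did not pass. Within single dates limma did not call Fos on date 1 (0.17, adjusted p = 0.306) or date 2 (0.40, adjusted p = 0.148), nor Atf3 on any date (0.48, 0.35 and 0.47, adjusted p = 0.0657, 0.263 and 0.132). Batf, Fosb and Jdp2 were not called on dates 2 and 3, with 3 arrays each. In the other direction, Fosl2 was called lower on date 1 (−0.28, limma adjusted p = 0.0491). The list lay 0.35 ± 0.18 above all genes in 11 of 12 tumours (exact sign-flip adjusted p = 0.00161). It did not stand apart from other genes with cameraPR (adjusted p = 0.148, and 0.314 with an estimated correlation). Within date 1 the shift was 0.34 with an exact sign-flip adjusted p of 0.0921. Of its 6 tumours only tumour 12 lay below 0 (−0.10), and the exact test over 6 arrays has few attainable p-values. Shifts of this size are open to dye bias, since no dye swap was analysed.

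**Figure D2:**
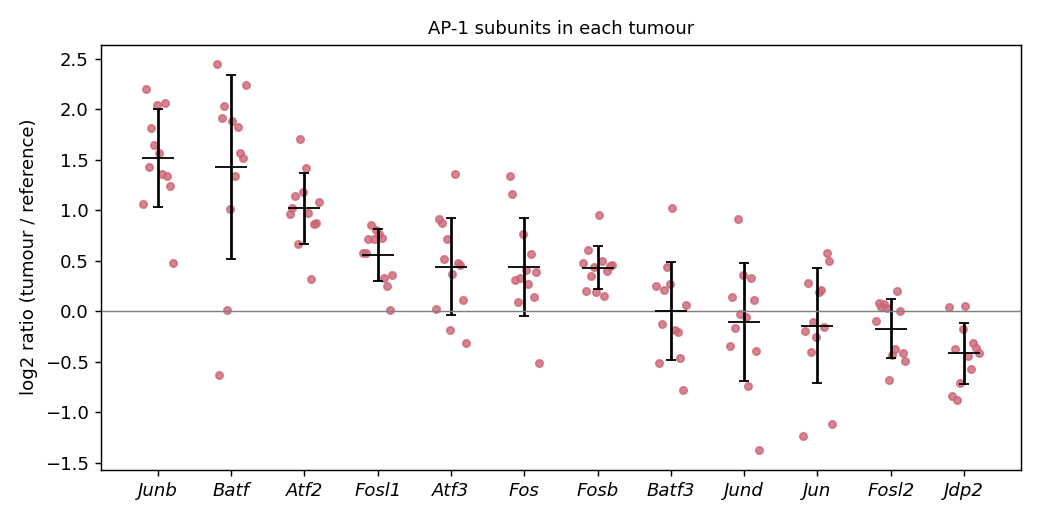
Log2 ratio of tumour over reference (vertical axis) for 12 AP-1 subunits, with 1 point per tumour, a horizontal tick at the mean of 12 tumours and a bar of 1 SD on each side. Junb lay above 0 in every tumour with a mean of 1.52, while Jun and Jund spread on both sides of 0.

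Genes linked to AP-1 and growth factor signalling did not share 1 direction. Among 16 other immediate-early genes 5 were higher and 6 lower. Ier3 (2.48 ± 0.98) and Myc (1.57 ± 0.43) were higher, and Klf4 (−1.84 ± 0.98) and Nr4a1 (−1.04 ± 0.94) lower. The list had a shift of −0.05 ± 0.32 (exact sign-flip adjusted p = 0.673), and 0.05 by the mean of its members. Among 14 AP-1-linked secreted and surface genes 6 were higher and 4 lower. The matrix metalloproteinase gene Mmp3 (2.64 ± 1.44) was higher, and Mmp13 (−2.95 ± 1.498), Mmp9 (−2.50 ± 0.70) and Hmox1 (−2.06 ± 0.69) were lower. That list had a shift of 0.11 ± 0.30 (exact sign-flip adjusted p = 0.272), and −0.15 by the mean. Of 12 RAS-MAPK output genes 9 were higher and 0 lower, with a shift of 0.53 ± 0.25 in 12 of 12 tumours (exact sign-flip adjusted p = 0.000911; cameraPR adjusted p = 0.0846). They include Phlda1 (2.66 ± 1.05), the ETS gene Etv4 (1.21 ± 0.84) and the phosphatase genes Dusp6 (1.15 ± 0.54) and Dusp4 (0.93 ± 0.76). Among 14 IGF, insulin and PI3K genes 4 were higher and 7 lower. Igfbp5 (1.94 ± 0.82) and Pik3r1 (1.75 ± 0.54) were higher, and Igfbp6 (−2.46 ± 0.25) and Igf2 (−1.77 ± 0.78) lower. The list had a shift of −0.12 ± 0.22 (exact sign-flip adjusted p = 0.116), −0.16 without tumour 7 (adjusted p = 0.0286) and −0.30 by the mean (adjusted p = 0.00410).

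Proliferation and interferon genes were higher than the reference, with a wide spread between tumours. Of 24 proliferation genes 18 were higher and 1 lower (20 and 1 when adjusted over the list alone), among them the mitotic kinase genes Plk1 (1.17 ± 0.43) and Aurka (1.00 ± 0.32) and the replication genes Pcna (0.89 ± 0.56) and Mcm7 (0.70 ± 0.49). The shift was 0.53 ± 0.51 in 11 of 12 tumours (exact sign-flip adjusted p = 0.0111), and 0.39 within date 1 (adjusted p = 0.239). Of 11 interferon-response genes 10 were higher, with a shift of 1.64 ± 1.16 in 11 of 12 tumours (exact sign-flip adjusted p = 0.00304). They include Irf7 (2.42 ± 1.25), Gbp2 (2.10 ± 0.77), Mx2 (1.99 ± 1.52) and Ifit1 (1.76 ± 1.67). The cameraPR calls of both lists were lost with an estimated correlation (adjusted p = 0.775 and 0.614). Among 11 hypoxia and glycolysis genes 5 were higher, such as Egln3 (1.67 ± 1.32), Adm (1.27 ± 1.51, and 0.73 within date 1, limma adjusted p = 0.204) and Pdk1 (1.18 ± 0.60), and 4 lower, such as Bnip3 (−1.45 ± 1.13). That list had a shift of 0.25 ± 0.53 (exact sign-flip adjusted p = 0.153). Of 8 Wnt target genes 5 were lower, among them Nkd1 (−3.39 ± 1.27), Dkk1 (−2.18 ± 0.28), Lef1 (−2.13 ± 1.66) and Lgr5 (−1.72 ± 0.69). The list fell by 1.10 ± 0.58 in 11 of 12 tumours (exact sign-flip adjusted p = 0.00161, and cameraPR adjusted p = 0.270). Tumour 5 was the exception, with a shift of 0.39.

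Stromal genes were lower than in the reference. All 13 fibroblast and collagen genes fell below it, including Lum (−4.95 ± 2.02), Pdgfra (−4.49 ± 0.69, n = 11), Dcn (−4.47 ± 1.01) and Col5a1 (−4.32 ± 0.73), and the list fell by 3.31 ± 0.54. All 10 adipocyte genes were lower, such as Cidec (−5.39 ± 0.92), Fabp4 (−4.66 ± 0.98), Plin1 (−4.64 ± 0.60) and the adiponectin gene Adipoq (−4.59 ± 0.70), and the list fell by 3.53 ± 0.52. All 10 genes of the epithelial-mesenchymal transition list were lower, among them Cdh2 (−3.17 ± 0.49), Twist1 (−3.10 ± 0.57), Twist2 (−3.05 ± 0.35) and Fn1 (−3.03 ± 1.04), and the list fell by 2.50 ± 0.40. Of 11 endothelial genes 10 were lower, including Cldn5 (−3.06 ± 0.72), Tek (−2.23 ± 0.42), Emcn (−1.87 ± 0.54) and Tie1 (−1.51 ± 0.33), and the list fell by 1.27 ± 0.27. Each of these 4 lists was lower in 12 of 12 tumours (exact sign-flip adjusted p = 0.000911). With an estimated correlation cameraPR kept the adipocyte (adjusted p = 0.00739) and transition lists (adjusted p = 0.00943). It lost the fibroblast (adjusted p = 0.126) and endothelial lists (adjusted p = 0.260).

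Macrophage, T and NK cell and B cell lists lay between −0.05 and 0.39 log2 units from all genes, and neutrophil genes were lower. Of 12 macrophage genes 7 were higher and 2 lower, with Aif1 (1.29 ± 0.61) and Fcgr1 (1.22 ± 0.78) higher and Mrc1 (−1.92 ± 1.06) and Lyz2 (−0.86 ± 0.70) lower. The shift was 0.39 ± 0.36 in 10 of 12 tumours (exact sign-flip adjusted p = 0.00576; cameraPR adjusted p = 0.254), and 0.28 by the mean (adjusted p = 0.0513). Among 11 T and NK cell genes 2 were higher, one of them Gzmb (0.71 ± 0.70), and 4 lower, among them Cd8b1 (−1.92 ± 0.61), Cd3d (−0.87 ± 0.67) and Gzma (−0.83 ± 0.83). That list had a shift of −0.05 ± 0.14 (exact sign-flip adjusted p = 0.261), −0.08 without tumour 7 (adjusted p = 0.0357) and −0.25 by the mean (adjusted p = 0.0196), while cameraPR pointed up (adjusted p = 0.880). Among 9 B cell genes 4 were higher and 1, Cd79b (−1.69 ± 0.57), lower. Cd22 (0.43 ± 0.24) was higher and Pou2af1 (−0.40 ± 1.19) did not pass, though on date 2 alone Pou2af1 was called lower (−1.26, limma adjusted p = 0.0208). Jchain was higher (0.66 ± 0.96, n = 11, limma adjusted p = 0.0300), and cross-hybridisation of its probe was not tested. It was not called without tumour 7 (0.61, adjusted p = 0.0598) or tumour 8 (0.65, adjusted p = 0.0510). Nor was Jchain called without both D14 tumours (0.63, adjusted p = 0.0767) or with date as a block (0.57, adjusted p = 0.105). Without tumour 3 its mean was 0.41. The B cell list had a shift of 0.11 ± 0.13 in 9 of 12 tumours (exact sign-flip adjusted p = 0.00889; cameraPR adjusted p = 0.695), and −0.05 by the mean. Among 9 neutrophil genes 6 were lower, such as the granule genes Camp (−4.65 ± 0.44), Mpo (−3.80 ± 0.23) and Ngp (−3.37 ± 0.37), and 2 higher, among them Ltf (3.62 ± 0.96), which is also a milk gene. The list fell by 1.59 ± 1.06 in 12 of 12 tumours (exact sign-flip adjusted p = 0.000911), a call lost in cameraPR with an estimated correlation (adjusted p = 0.126).

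Lists of other tissues showed what the reference held above the tumours. All 12 skeletal muscle genes were lower, including Tnnt1 (−5.36 ± 0.21) and Myh2 (−5.21 ± 0.29), and the list fell by 3.98 ± 0.18. Of 12 liver genes 11 were lower, such as Afp (−5.77 ± 0.47) and Apoa1 (−4.85 ± 0.29), and 1 higher, and the list fell by 3.96 ± 0.24. All 10 neuron genes were lower, such as Tubb3 (−5.27 ± 0.42) and Nefl (−4.69 ± 0.42), and the list fell by 4.25 ± 0.26. All 5 erythroid genes were lower, such as Slc4a1 (−3.74 ± 0.29) and Alas2 (−3.41 ± 0.53), and the list fell by 2.37 ± 0.22. All 8 cornified epidermis genes were lower, such as Lce1a1 (−5.16 ± 0.40) and Krt10 (−4.81 ± 0.17), and the list fell by 2.90 ± 0.40. Of 8 cartilage and bone genes 6 were lower, such as Ibsp (−4.73 ± 0.49) and Col2a1 (−4.09 ± 0.83), and 1 higher, and the list fell by 1.93 ± 0.30. Each was lower in 12 of 12 tumours (exact sign-flip adjusted p = 0.000911), and all but the cartilage and bone list (adjusted p = 0.0959) passed cameraPR with an estimated correlation. In all, 22 of 28 lists passed the sign-flip test, 9 up and 13 down. That test asks whether a shift is steady over the tumours, and cameraPR whether a list stands apart from other genes. Of the 16 that passed cameraPR with the preset correlation, 10 passed with an estimated one. Adjusted over the list alone, 14 milk genes were higher, and outside the milk and proliferation lists the counts matched those over all genes.

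Between tumours, a small part of the genes varied widely. The SD over 12 tumours had a median of 0.33 log2 units, and 418 of 16431 genes (2.54%) had an SD over 1. The 10 largest belonged to the surfactant protein gene Sftpd (2.47), the BMP and Wnt antagonist gene Sostdc1 (2.25), Fndc1 (2.11), Vit (2.08), Pipox (2.08), the Wnt inhibitor gene Wif1 (2.07), Gsta3 (2.03), Lum (2.02), the haptoglobin gene Hp (2.01) and Ly6d (1.998). For 1247 genes with a pair of probes, the median correlation of the pair across tumours was 0.245. It was 0.0167 for genes at or below the median SD of these and 0.801 for the 125 with the largest SD, so that small differences between tumours were mostly not reproduced by a second probe. Among list scores, proliferation, fibroblast, macrophage, hypoxia and neuron genes varied more than all or nearly all of 10000 random lists (percentile 100), as did T and NK cell (99.99), interferon-response (99.98) and endothelial genes (99.98). Liver (99.93) and luminal epithelial genes (99.92) lay nearly as high. Since random members were matched on SD, the percentile measures how far the genes of a list move together. The SD of the proliferation score was 0.51, and 0.25 without tumour 7. The neuron score fell with the slope of an array's muscle and liver ratios on those of the other tumours (r = −0.706, permutation p = 0.0115, n = 12, tested after seeing the scores), so its spread partly follows the scale of the ratios. With neuron genes in the slope r was −0.882, and the score was −0.37 in tumour 5 (slope 1.07) and 0.40 in tumour 7 (slope 0.924). AP-1 subunits lay at percentile 69.8. The interferon-response score ran from −1.79 in tumour 5 to 1.25 in tumour 4, and the proliferation score from −1.43 in tumour 7 to 0.51 in tumour 12.

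**Figure D3:**
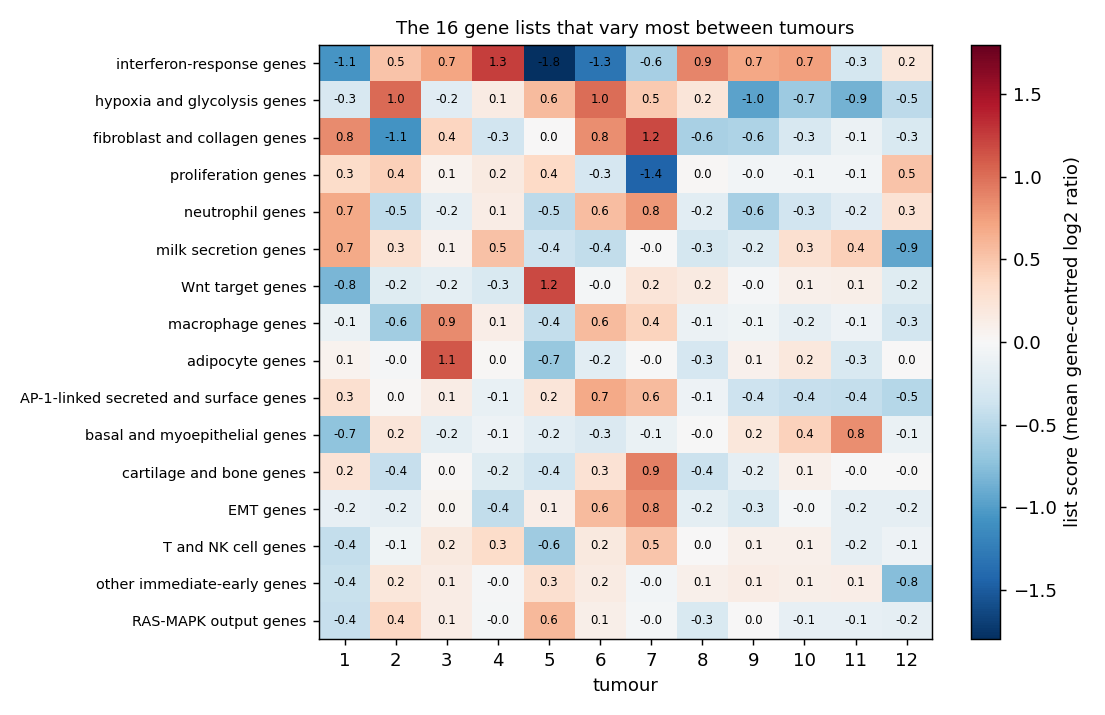
List score, the mean gene-centred log2 ratio, of the 16 lists that varied most (vertical axis) in tumours 1 to 12 (horizontal axis), on a colour scale from −1.8 to 1.8 log2 units. The interferon-response score was lowest in tumour 5 at −1.79, and the proliferation score lowest in tumour 7 at −1.43.

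AP-1 subunit scores were set against other scores over the 12 tumours, among 16 planned pairs. No pair passed after Benjamini-Hochberg adjustment, and 1 had an unadjusted Pearson permutation p under 0.05. AP-1 subunits and AP-1-linked genes had r = 0.639 (permutation p = 0.0208, adjusted 0.315) and rho = 0.692 (permutation p = 0.0157, adjusted 0.125). Without tumours 7 and 12, the farthest in AP-1 score, r was 0.371 (permutation p = 0.294), and within date 1 it was 0.880 (exact permutation p = 0.0181, n = 6). AP-1 subunits and macrophage genes had r = 0.577 (permutation p = 0.0516, adjusted 0.315) and rho = 0.713 (permutation p = 0.0119, adjusted 0.125). Their r was 0.604 without the same tumours and 0.754 within date 1 (exact permutation p = 0.0819, n = 6). AP-1 subunits and proliferation genes had r = −0.630 (permutation p = 0.0610, adjusted 0.315) and rho = −0.343 (permutation p = 0.274, adjusted 0.566). Their r was −0.778 within date 1 (exact permutation p = 0.0889, n = 6) and 0.00410 without tumours 7 and 12. Other AP-1 pairs also moved without these 2 tumours. With basal and myoepithelial genes r went from −0.300 (permutation p = 0.333) to −0.697 (permutation p = 0.0282, not adjusted). With other immediate-early genes r went from 0.502 (permutation p = 0.118) to −0.224 (permutation p = 0.464). Among the planned pairs without AP-1, luminal epithelial and fibroblast genes had rho = −0.594 (permutation p = 0.0452, adjusted 0.240). Their r was −0.391 (permutation p = 0.209), and −0.668 without tumours 9 and 12 (permutation p = 0.0353, not adjusted).

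Tumours 6 and 7, which share D14 in their titles, had the highest Pearson correlation of the 66 pairs, and ranked 3 of 66 by Spearman. Over 16431 gene-centred ratios their correlation was 0.464 (exact one-sided p = 0.0152, the smallest possible), against 0.453 for the next pair, tumours 10 and 11, and a median of −0.0772 for the other 65. Spearman's rho of the pair was 0.293 (exact one-sided p = 0.0455), against 0.448 for the highest pair. The correlation is across genes, which are not independent replicates. They carry different dates, and with genes centred within date the pair had r = 0.591. After each gene was regressed on the fibroblast and proliferation scores, a setting added after seeing the data, the correlation of the pair was −0.278, rank 53 of 66 (exact one-sided p = 0.803). In that regression tumour 7 had a leverage of 0.800 and kept 8.88% of its sum of squares, so its outcome was nearly fixed. Without the genes of the proliferation and fibroblast lists r was 0.462, but these are 23 and 12 of the 16431 genes, too few to move it. The first principal component, 22.9% of the variance, placed tumours 6 (49.3) and 7 (58.4) highest.

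Few genes passed the test between the 3 dates. limma's F test called 5 of 16881 genes past adjusted p. An unadjusted p under 0.05 was found for 2616 genes (15.5%), a larger share than the 0.05 expected on average with no difference between dates. In simulated data with a shift on date 1 alone, this design recovered 42% of genes shifted by 1 log2 unit and 0% of those shifted by 0.5. Smaller differences were therefore mostly not detectable. The 5 were C130074G19Rik, Endou, Gnat2, Olfr622 and Cyp3a41a, each with adjusted p = 0.0470, the last named because the count is so small. Mean log2 ratios of Endou were −1.45, 0.57 and −2.55 on dates 1, 2 and 3, and those of Olfr622 were 0.35, 0.74 and 2.44. The count was 0 with quantile normalization or without the D14 tumours, and without tumour 9 it was 43. No gene passed without tumour 1, 2, 3, 4, 6, 8, 10, 11 or 12, and 2 passed without tumour 5.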

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

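Fits without both D14 tumours, the variation without each tumour and the regression setting were chosen after seeing the data. Counts against the reference stayed within 1.5 times their values under all alternatives but a few within single dates. There limma called 5901 genes (date 2) and 6293 (date 3), and 1514 beyond 2-fold (date 2), from fewer arrays. Without 1 tumour the counts ran from 10898 to 11281 and from 2280 to 2378, and without both D14 tumours they were 11099 and 2388. The AP-1 shift ran from 0.32 to 0.39 without 1 tumour and was 0.34 within date 1 (exact adjusted p = 0.0921, 6 arrays). The B cell shift turned to −0.0503 by the mean. With an estimated correlation cameraPR called 10 lists instead of 16. Between dates limma called 0 genes after quantile normalization and 0 without the D14 tumours, and 0 to 43 without 1 tumour, against 5. The cause was not tested. The likeness of the D14 tumours ranked 3 of 66 by Spearman, and its r turned to −0.278 after regression on the fibroblast and proliferation scores. It was 0.462 without the genes of these lists, which are too few to move it. Neither setting decides whether a shared stromal and proliferation level accounts for the likeness. Of the 10 genes with the largest SD, 6 stayed by the range without the extreme tumours, and 6 to 9 without 1 tumour. Calls of list shifts were lost in 8 leave-one-out settings, all for basal genes, in 3 settings within date 1 beside AP-1 (basal, proliferation and B cell genes) and in 3 others (basal and macrophage genes). In the leave-one-out settings the basal shift was −0.36 to −0.26, against −0.36 with all tumours, and it was −0.36 with the D14 tumours averaged and −0.35 without them. Within date 1 the shifts were −0.22 (basal), 0.39 (proliferation, against 0.53) and 0.12 (B cell, against 0.11), from 6 arrays. Over 6 arrays the exact test has few attainable p-values. The macrophage shift was 0.28 by the mean, against 0.39. Named genes lost 56 calls within single dates and 4 elsewhere. On date 1 these were Fos (0.17 against 0.44), Cited1 (−0.02 against −0.29), Adm (0.73 against 1.27), Hp (−0.93 against −1.99), Atf3 (0.48 against 0.44) and Jchain (0.90 against 0.66). On date 2 the means of Ifit1 (0.60 against 1.76), Bnip3 (−0.45 against −1.45), Lyz2 (−0.24 against −0.86), Nr4a1 (−0.43 against −1.04), Fcgr1 (0.50 against 1.22), Fndc1 (−1.18 against −2.77), Lef1 (−1.02 against −2.13) and Mx2 (0.98 against 1.99) also shrank, as did Gsta3 (−0.63 against −2.32), Gzmb (0.30 against 0.71) and Jchain (0.32) on date 3. Named genes also gained 4 calls within single dates, 1 without 1 tumour and 4 in other settings. Examples are Vit without both D14 tumours (−1.50, limma adjusted p = 5.73e-05), Sftpd on date 3 (2.81, limma adjusted p = 0.00796) and Pou2af1 on date 2 (−1.26, limma adjusted p = 0.0208). Log base, direction, dye bias and background limit all ratios against the reference.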

Other observations

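Apart from the centring within dates, the tests in this part or their criteria were chosen after the results they bear on had been seen, from scanning 28 list scores in 12 tumours and single-tumour gaps over 16431 genes. Tumours 6 and 7 lay at least 1 log2 unit apart from the other 10 on 82 genes, against 8 for the next pair. Above the others were the prolactin family gene Prl2c3 (4.72 against 0.49 ± 0.27, n = 10), Vit (3.46 against −1.50 ± 0.84), Aox3 (1.08 against −3.35 ± 0.66) and Spink8 (4.05 against −0.46 ± 0.56). Below were the cyclin gene Ccnd1 (−1.43 against 1.41 ± 0.58), Slain1 (−2.17 against 0.64 ± 0.37) and Id4 (−3.44 against 0.81 ± 1.04). Single tumours stood apart for Pip, 2.45 in tumour 1 and at most −3.29 elsewhere, for Armc8, −6.81 in tumour 7 against −0.11 ± 0.28 (n = 11), and for Jchain, 3.26 in tumour 3 against 0.41 ± 0.44 (n = 10). In tumour 5 Xist was −4.97 against 0.55 ± 0.61 (n = 11), with the Y-linked gene Eif2s3y at −5.08, inside the range of the others.

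The interferon-response score correlated at r = 0.515 with T and NK cell genes (permutation p = 0.0847, adjusted 0.169, rho = 0.399, permutation p = 0.200), r = 0.406 without tumours 5 and 6 and −0.290 within date 1. Its r with macrophage genes was 0.00710 (rho = 0.126). With fibroblast genes r was −0.619 (permutation p = 0.0339, adjusted 0.136, rho = −0.664), −0.701 without the same tumours and −0.645 within date 1. With proliferation genes r was 0.145 (rho = 0.049), 0.2975 without the same tumours and 0.621 within date 1. None of these 4 relations passed adjustment. The SD of the score within dates was 1.02 of that over all tumours. Whether immune cell content sets the score stayed undecided.

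Tumour 7 had the lowest value of the 12 tumours for all 23 proliferation genes measured on every array, with a median deviation of −1.52 ± 0.10 (bootstrap SE over genes). A lower share of tumour cells would lower luminal genes as well, unless other luminal cells took their place. The median luminal epithelial gene deviated by −0.0958 ± 0.0915 (score −0.20, lower only in tumour 12 at −0.49). The median alveolar and luminal progenitor gene deviated by −0.31 ± 0.20 (score −0.39, lowest of the 12). Compressed ratios on this array would flatten the muscle, liver and neuron genes. Their slope on the other tumours was 0.924, a small flattening but the lowest of the 12, the other arrays running from 0.954 to 1.07. For genes far below 0, such as liver and neuron genes, such a slope by itself gives higher values. Fibroblast (1.07 ± 0.15), neutrophil (0.62 ± 0.21), T and NK cell (0.57 ± 0.09), endothelial (0.43 ± 0.20), neuron (0.34 ± 0.08), macrophage (0.32 ± 0.09) and liver genes (0.26 ± 0.12) lay higher, adipocyte (0.08 ± 0.12) and B cell genes (−0.04 ± 0.18) near their means and interferon-response genes lower (−0.57 ± 0.21). The luminal values argue against non-luminal cells in place of tumour cells as the whole cause, and the slope against compression as the whole cause. The luminal values cannot exclude luminal cells that are not tumour cells, since such cells would hold the luminal genes up. Compression draws ratios towards 0 and does not change their sign. The shift of the proliferation list was −0.91 in tumour 7 against 0.21 to 1.05 in the others, which argues against compression for this fall. A partial share of a lower tumour cell content stays open, and the fibroblast score was highest in tumour 7 (1.18). No biological explanation was tested, as the design names none.

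Tumour 5 had the highest value for 15 of 20 measured hair genes, but not for Krt35, Krt71, Krt82, Hoxc13 and Foxn1: Krt27 was 1.55 against −3.16 ± 0.42 (n = 11), Krt33a 3.04 against −1.64 ± 0.32, Krtap9-3 3.75 against −0.27 ± 0.31 and Krtap15 3.61 against −0.34 ± 0.32. A list of 28 hair genes was written once this was seen. Of the 8 measured members not looked at before, 7 were highest in tumour 5 (one-sided exact binomial p = 2.07e-07, for genes that are not independent), which argues against a fault of a few probes. Skin in the sample would raise cornified epidermis genes, but their median deviation was −0.375 ± 0.196 and 2 of 8 lay above the mean of the other tumours, although the list shift, −2.51 against a mean of −2.90 over all tumours, was the second highest. Hair follicles without epidermis may still be the source, and a source within the tumour cells was not tested. Keratin probes that cross-hybridise stay open as well, since the 8 members not looked at before are all keratin genes. S100a3 (0.74 against −1.53 ± 0.33), Padi3 (1.43 against −0.87 ± 0.33), Msx2 (1.68 against −1.47 ± 0.71) and the Wnt target gene Nkd1 (0.36 against −3.73 ± 0.48) are no keratins and were highest in tumour 5. They had been looked at before, so they cannot test this, and Hoxc13 and Foxn1, also no keratins, were not highest there.

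The likeness of tumours 6 and 7 was not due to a shared date: they carry dates 2 and 1, and centring within dates gave r = 0.591 against 0.287 for the next pair. Whether a shared level of stromal and proliferation genes accounts for it stayed open. Regression on both scores took r to −0.278, rank 53 of 66, but decides nothing, by a leverage limit of 0.5 set after the value was seen: tumour 7 had a leverage of 0.800 and kept 8.88% of its sum of squares. Whether D14 marks 1 animal is not given in the sources used here.

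For the 5 genes called between dates, 5 of 100 splits of the tumours into groups of 6, 3 and 3, the real one included, gave at least as many genes, and the highest of the others gave 23. Chance was not excluded for that count, since that share is not under 0.05. The larger number of genes with an unadjusted p under 0.05 was not set against the splits.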
